A study of Caenorhabditis elegans with 2 samples.

How the data were processed

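Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans embryos of mixed stages and mixed sex. The strain, OP64, carries a mutation in unc-119 and a transgene that makes HLH-1 fused to eGFP. HLH-1 is the worm's member of the MyoD family of basic helix-loop-helix (bHLH) muscle factors. Such factors bind E-boxes, DNA sites of the form CANNTG. Per the labels, 2 biological replicates form 1 group, the size range of the fragments was 150 to 350 bp and a control library exists. The control was not analysed here. The labels name the target of the antibody as hlh-1 and describe the experiment as ChIP against the eGFP fusion.

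All files used were peak lists. Per the deposited manifest, each replicate has a relaxed list that holds peaks together with background, meant as input to a test of reproducibility (irreproducible discovery rate, IDR). A relaxed list was also made from the pooled alignments, and the list past the IDR threshold, called the IDR list here, was derived from the pooled list and both replicates' lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The authors gave each peak a score, which is not stated to be a fold enrichment, so it was used only to rank or describe peaks within a list and, as log10 values, for correlations across peaks. The authors also gave each peak a −log10 q-value, which reaches the same highest value of 3.319 in 96.1% of the IDR list and was therefore not used for ranking. Read depth is not given in the sources used here, so the precision of any score is unknown and the intervals below cover counting of peaks or genes alone.

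The lists on the ce11 build were used throughout, since the reference sequence (WBcel235) is that build, and no IDR peak lies beyond the end of its chromosome. Lists on ce10 served only for an alternative count and correlation, and no coordinates were converted. Coordinates are 1-based. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes; the position of mir-1 came from the RefSeq annotation of the same assembly. The start of a gene is its most 5′ annotated base.

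The share of peaks on each chromosome was compared with its share of the nuclear length by exact two-sided binomial tests. Overlap of the replicates was measured over the top 3254 peaks by score of each list, as many as the IDR list holds, with a minimum overlap of 1 bp. It was set against 1000 circular shifts within chromosomes in a one-sided permutation test. Sequence was tested in the 101 bp centred on each summit against the 101 bp centred 500 bp to its right with an exact two-sided McNemar test, for the 10 distinct E-box hexamers. Each of the 2080 distinct hexamers, with reverse complements merged, was ranked by its ratio of summit windows to flank windows. Fisher's exact test compared CAGCTG between the 650 highest-scoring and the 650 lowest-scoring peaks. A protein-coding gene was called bound when a summit lay from 2000 bp upstream to 500 bp downstream of its start. Bound shares of 13 gene lists, fixed before the data were examined, were compared with those of all other protein-coding genes by Fisher's exact test. Of the listed symbols, 1 (tmd-1, in the list of 30 sarcomere symbols) matched no gene; it seems to be an older name of unc-94, which is in the list, although the annotation does not record it. Non-coding genes with a summit inside the gene or within 250 bp of either end were compared with protein-coding genes with a summit within 250 bp of the start. The windows of the non-coding genes are longer by the gene itself, which can only raise their shares. Benjamini-Hochberg adjustment was made within each family of tests. Genes and peaks are not replicates, so each p-value compares sets within the lists at hand and says nothing about the spread between animals. Intervals of shares are 95% Wilson intervals.

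The genes named are those nearest to the 15 strongest peaks, up to 4 bound members with the strongest peaks and up to 3 unbound members in alphabetical order per list, and hlh-1, unc-119, unc-120, hnd-1, hlh-8, unc-54, myo-3, unc-15 and mir-1. This rule was fixed before the data were examined. The plan had taken the authors' peak value for an enrichment; it is a score of unknown scale, so ranks replaced folds.

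Alternatives were other windows (51 and 201 bp), the left flank, the upper part of the list by score, top 3254 peaks of either replicate alone, and other distances to genes. For the gene lists they also included the nearest start only, whole gene bodies, and a Mantel-Haenszel test stratified by the distance to the next gene upstream. A further alternative, chosen after seeing the data, kept only the 1567 IDR peaks that overlap a top peak in both replicates. The tests were tried on simulated data. In 20 runs with 500 of 3254 peaks placed on CAGCTG and peaks beside 80% of the genes of 3 lists, the motif was called in 20 runs, and 60 of 60 tests of planted lists and 3 of 200 tests of other lists were past the threshold. With peaks placed at random, 0 of 20 motif tests, 1 of 20 tests of CAGCTG by peak strength and 1 of 260 list tests were past it. These random peaks were drawn evenly along the chromosomes, whereas the real summits lie mostly between genes and near starts. The runs therefore do not show how often the tests err with peaks placed like the real ones. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.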

Results

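HLH-1 binding was mapped in C. elegans embryos of mixed stages by ChIP-seq of an eGFP fusion, in 1 group of 2 biological replicates with no second condition. The question the design addresses is where the tagged muscle factor binds. The IDR list held 3254 peaks on ce11, with a median width of 296 bp and scores from 32.5 to 964.9 (median 55.7). These peaks covered 0.914% of the nuclear genome, and neighbouring summits lay a median of 15765 bp apart. The list consisted of the 3254 highest-scoring peaks of the pooled relaxed list, which held 25321. The relaxed lists held 28959 peaks for replicate 1, with scores up to 165.7, and 30000 for replicate 2, with scores up to 806.3. Read depth behind these lists is not given in the sources used here.

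The 2 strongest peaks of the list lay at hlh-1 itself. The strongest (chromosome II, 4518335 to 4518745, score 964.9) had its summit at 4518550 in intergenic sequence, 24 bp upstream of the hlh-1 start. The next (4519979 to 4520349, score 910.0) had its summit at 4520141 in an hlh-1 intron, 1567 bp downstream of the start. They ranked 1 and 2 in both replicates, with scores of 165.7 and 148.6 in replicate 1 and 806.3 and 774.5 in replicate 2. The intronic summit window held CAGCTG at 4520146 to 4520151, within ACTTATCTCAGCTGCTCCTTGC, and the promoter window held the E-box CAGTTG at 4518559 to 4518564, within TGAAGTGTCAGTTGTGCTCATC. Within 20 kb of the hlh-1 start lay 8 summits, against a median of 1 over all protein-coding starts. The transgene may add copies of this locus, so these peaks may in part be technical, as taken up below.

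**Figure D1:**
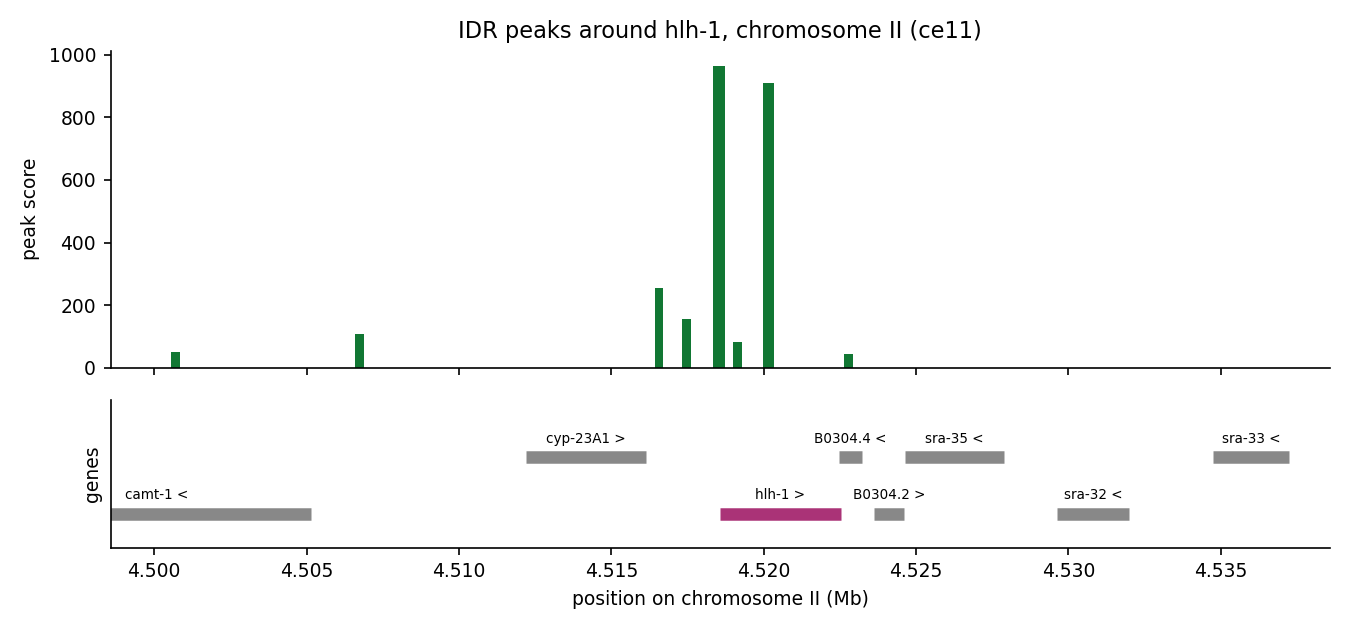
IDR peaks within 20 kb of the hlh-1 start on chromosome II (ce11), drawn to scale along the x axis in Mb, with the authors' peak score on the y axis and annotated protein-coding genes below (> plus strand, < minus strand). The 2 peaks with scores of 964.9 and 910.0 stand at the start and in an intron of hlh-1, and the other 6 have scores from 45.3 to 254.

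The remaining peaks among the 15 strongest lay beside genes of several kinds. The histone H3.3 gene his-72 had peaks ranked 4 (chromosome III, summit 12369670, intergenic, 620 bp upstream of the start, score 408.6) and 10 (summit 12369028, in an intron, 22 bp downstream of the start, score 339.1). A peak with a score of 353.6 lay 3670 bp upstream of sup-12, which encodes a muscle splicing regulator (chromosome X, summit 3900914). A peak with a score of 338.3 lay 2365 bp upstream of tln-1, the talin gene (chromosome I, summit 1719225). The summit nearest to unc-14 (chromosome I, 7128344, score 331.0) was 98 bp upstream of its start. The others had their nearest starts at tol-1 (10310 bp, score 439.8), txt-14 (662 bp, score 393.5), Y116F11B.14 (1689 bp, score 370.4), tag-278 (260 bp, score 351.2) and R05D7.2 (636 bp, score 326.8), all downstream of the summit. For ppfr-1 (15215 bp, score 361.4), R06C1.4 (3563 bp, score 320.2) and M05D6.9 (4906 bp, score 309.5) the start lay upstream of the summit. Of the 15 summit windows, 9 held CAGCTG.

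Genes that build and run body wall muscle were bound far more often than other genes. Of the sarcomere genes 25 of 29 were bound (86.2%, interval 69.4 to 94.5), of the genes for muscle attachment 18 of 25 (72%, 52.4 to 85.7) and of those for muscle excitation 18 of 22 (81.8%, 61.5 to 92.7). Among all protein-coding genes 2553 of 19973 were bound (12.8%). The odds ratios against all other protein-coding genes were 43.1 (adjusted p = 2.56e-18), 17.7 (adjusted p = 4.01e-11) and 30.9 (adjusted p = 1.12e-12), by Fisher's exact test with Benjamini-Hochberg adjustment over 13 lists. With the top peaks of replicate 1 alone the counts were 18 sarcomere, 15 attachment and 11 excitation genes, with odds ratios of 14.7, 13.5 and 8.96, all still past the threshold. Over all alternatives the odds ratio ranged from 11.9 to 29.7 for attachment and from 8.96 to 58.3 for excitation genes.

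In the sarcomere list the strongest peaks lay at unc-27, a troponin I gene (chromosome X, 8789137 to 8789331, 248 bp upstream of the start, score 290.3), and at ttn-1, which encodes a titin-like giant protein (chromosome V, 6204205 to 6204343, 1656 bp upstream, score 220.9). Next came tnt-3, for troponin T (chromosome X, 7945550 to 7945709, 539 bp upstream, score 191.5), and pat-10, for troponin C, whose summit at 5020233 on chromosome I lay in its 5′ UTR, 125 bp downstream of the start (score 189.0). The sarcomere genes act-2, alp-1 and tni-1 were not bound, and neither was unc-94, which was named after its values were seen. The myosin heavy chain genes unc-54 and myo-3 and the paramyosin gene unc-15 were bound, each with summits both upstream of the start and in an intron. At unc-54 (chromosome I) the summits lay 96 bp upstream (14863578, intergenic, score 84.7), 1563 bp upstream (14865045, score 54.7) and 1142 bp downstream of the start (14862340, intron, score 61.6). At myo-3 (chromosome V) they lay 443 bp upstream (12234786, score 71.1), 1345 bp upstream (12235688, score 95.5) and 740 bp downstream (12233603, intron, score 97.4), and the peak at 443 bp had no counterpart in the replicate 1 list. At unc-15 (chromosome I) the summits nearest to the start were 166 bp upstream (7383363, score 58.5), 1316 bp upstream (7384513, in the 5′ UTR of C15A11.2, score 45.1) and 2028 bp downstream (7381169, intron, score 104.7).

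Among attachment genes, the type IV collagen gene emb-9 (1894 bp upstream, score 240.4), the kindlin gene unc-112 (429 bp upstream, score 218.4), the dystrophin gene dys-1 (1578 bp upstream, score 210.5) and tln-1 (802 bp upstream, score 172.9) had the strongest peaks in their windows. The genes lim-8, lim-9 and pat-2 were not bound. In the excitation list the strongest were unc-29, an acetylcholine receptor subunit (1204 bp upstream, score 197.2), unc-93 (573 bp upstream, score 124.7), the potassium channel gene shk-1 (367 bp upstream, score 108.9) and the ryanodine receptor gene unc-68 (1445 bp upstream, score 106.1). No summit fell in the windows of acr-16, cca-1 or the calcium channel gene egl-19. The muscle microRNA mir-1 (chromosome I, 6172662 to 6172757) had a summit 535 bp upstream of its start, at 6173292 in intergenic sequence (score 80.5).

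Transcription factors of the muscle lineage were not distinguished from other genes. Of 12 myogenic regulators 2 were bound (16.7%, interval 4.70 to 44.8; odds ratio 1.37, exact adjusted p = 0.714), hlh-1 itself and the serum response factor gene unc-120 (chromosome I, summit 8459088, 1137 bp upstream of the start, score 91.6). The hlh-1 locus may be copied by the transgene, which may give peaks for a technical reason, so this count rests partly on that locus. With the top peaks of replicate 1 alone 3 of 12 were bound (odds ratio 2.98, exact adjusted p = 0.210). Of the unbound members, ceh-51, fozi-1 and hlh-2 come first in the alphabet. The bHLH genes hnd-1 and hlh-8 were also unbound, with the nearest summits 8681 bp downstream and 6314 bp upstream of their starts.

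Few listed genes of other tissues were bound. None of 12 pharyngeal muscle genes (interval up to 24.2%), 23 intestinal genes (up to 14.3%) or 21 epidermal genes (up to 15.5%) was bound, with exact adjusted p = 0.50, 0.119 and 0.157, so that these lists were not distinguished from other genes. Examples are the pharyngeal genes ceh-22, myo-1 and myo-2, the intestinal genes act-5, asp-1 and cpr-1, and the epidermal genes ajm-1, bli-1 and che-14. Of 29 neuronal genes 2 were bound, unc-44 (score 56.3) and unc-33 (score 35.9), and aex-3, cat-2 and cha-1 were not (exact adjusted p = 0.679). Of 21 germline and early embryo genes mex-1 (score 101.2) and cgh-1 (score 61.5) were bound, and car-1, gld-1 and glh-1 were not (exact adjusted p = 1). Cuticle collagens, with 6 of 156 bound (odds ratio 0.271, exact adjusted p = 0.000541), and chemoreceptors, with 17 of 1013 bound (odds ratio 0.110, adjusted p = 7.89e-39), were bound less often than other genes. With the top peaks of replicate 1 alone 22 chemoreceptor genes (odds ratio 0.189, exact adjusted p = 1.09e-22) and 3 neuronal genes (odds ratio 1.03) were bound. The strongest collagen peaks lay at col-94 (score 102.4), col-38 (49.8), col-8 (41.0) and col-55 (39.2), and those of the chemoreceptors at srz-42 (score 147.4), srt-63 (114.6), sri-19 (98) and srd-43 (89.4). Of 72 histone gene entries 14 were bound (odds ratio 1.65, exact adjusted p = 0.157), led by his-72, his-35, his-37 and his-31. Whether repeated histone sequences affect the placement of peaks was not tested.

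Ribosomal protein genes, which are used in every cell, were also bound at a high rate. Of 78 such genes 68 were bound (87.2%, interval 78 to 92.9; odds ratio 47.6, exact adjusted p = 3.56e-49). The strongest peaks lay at rpl-43 (739 bp upstream of the start, score 141.5), rpl-34 (417 bp, score 136.7), rps-28 (440 bp, score 134.2) and rpl-3 (253 bp, score 133.8). The genes rpl-17, rpl-25.1 and rpl-25.2 were not bound. With the top peaks of replicate 1 alone 43 of the 78 were bound, and the odds ratio was 11.2. Assigning each summit to its nearest start alone left 38 of the 78 bound (48.7%), with an odds ratio of 8.82 (exact adjusted p = 9.84e-18). The same setting left 23 of 29 sarcomere, 16 of 25 attachment and 19 of 22 excitation genes bound. Many ribosomal protein genes were thus called bound through summits nearer to another start.

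**Figure D2:**
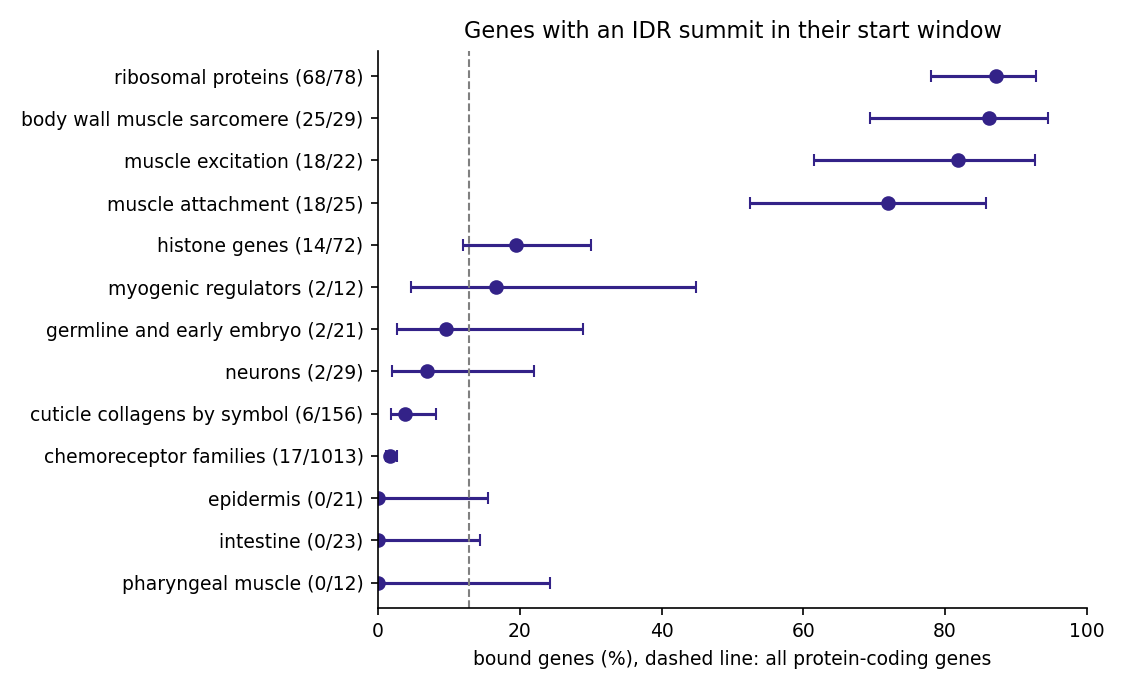
Percent of protein-coding genes with an IDR summit from 2000 bp upstream to 500 bp downstream of the start (x axis) for 13 gene lists (y axis, bound genes over members in parentheses), with points for the share, bars for the 95% Wilson interval and a dashed line for all protein-coding genes (12.8%). Ribosomal protein genes and 3 muscle lists lie between 72% and 87.2%, and pharyngeal, intestinal and epidermal genes at 0%.

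The E-box CAGCTG marked the summits. It occurred in 496 of 3254 summit windows (15.2%, interval 14.1 to 16.5) and in 54 flank windows (1.66%), a ratio of 9.19 (exact McNemar test, adjusted p = 8.28e-92 over 10 E-boxes). This ratio ranked 1 among all distinct hexamers. It was 5.83 with the top peaks of replicate 1 alone and 17.1 with the peaks found in both replicates' top lists. The sites lay a median of 15.5 bp from the summit, and 351 of 516 were within 25 bp. Also above their flanks were CAACTG (586 against 166 windows, ratio 3.53, exact adjusted p = 5.21e-61), CACCTG (307 against 87, ratio 3.53, adjusted p = 6.96e-31), CACATG (ratio 2.52), CAAGTG (2.30), CAGATG (1.84), CATATG (1.83) and CACGTG (1.43). CAAATG (exact adjusted p = 0.0613) and CAATTG (adjusted p = 0.159) were not. By the ratio of summit to flank windows, CAACTG and CACCTG ranked 89 and 90 among all distinct hexamers. CACATG ranked 254, CAAGTG 325, CAGATG 508, CATATG 516 and CACGTG 807. CAATTG, with a ratio of 1.18, ranked 1035. Ratios above 1 were thus common among hexamers, and a modest excess over the flank was not particular to E-boxes. At least 1 of CAGCTG, CAACTG and CACCTG was present in 1261 summit windows (38.8%) and in 300 flank windows (9.22%). Hexamers without an E-box also ranked high, among them GCGCGC (ratio 8.13), GACGCA (7.13), ACGCAG (6.82), CGTCTC (6.57) and GAGAGA (966 against 168 windows, 5.75).

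Stronger peaks carried CAGCTG more often. It was present at 31.1% of the 650 summits with the highest scores (interval 27.6 to 34.7) and at 8.46% of the 650 with the lowest, a difference of 22.6 percentage points (Fisher's exact test, two-sided, p = 2.03e-25). The shares were 23.2% and 3.85% with the top peaks of replicate 1 alone (odds ratio 7.57, against 4.88 in the main analysis). Among the 297 peaks of other widths than the one 2957 peaks share, 41.4% held CAGCTG, against 12.6% of the others. Their median score was 166.6, against 53.1 for the others, so width was not separated from strength here.

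**Figure D3:**
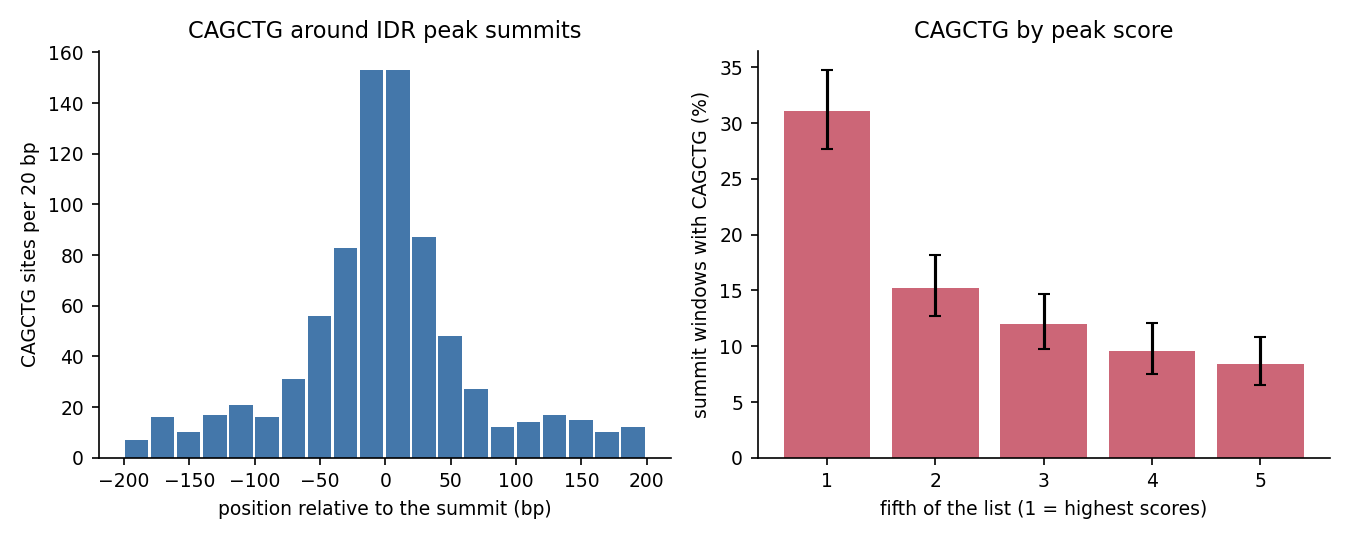
Left, number of CAGCTG sites per 20 bp (y axis) by position relative to the summit in bp (x axis) over 3254 IDR peaks, with 153 sites in each of the 2 central bins. Right, percent of summit windows with CAGCTG (y axis) in 5 equal parts of the list by score (x axis, 1 the highest), with 95% Wilson intervals, from 31.1% to 8.41% (the last part holds 654 peaks, the others 650).

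Peaks beside muscle genes and beside ribosomal protein genes were not distinguished by CAGCTG. It was present at 9 of 79 summits beside muscle genes (11.4%, interval 6.11 to 20.3) and at 5 of 67 beside ribosomal protein genes (7.46%, interval 3.23 to 16.3), a difference of 3.93 percentage points (Fisher's exact test, two-sided, p = 0.575). Replicate 1 alone had it at 2 of 56 muscle summits (3.57%) and 3 of 43 ribosomal protein summits (6.98%), a difference of -3.41 points (exact p = 0.650). Beside muscle genes the motif exceeded its flank (9 against 1 window, exact McNemar p = 0.00781), and beside ribosomal protein genes this was not detectable (5 against 2, exact p = 0.453). At the 33 summits in the windows of sarcomere genes there was no CAGCTG (interval up to 10.4%). CAACTG was present at 8 of them (24.2%) and in 1 of their flanks (exact McNemar p = 0.0391, not adjusted). Its share was not distinguished from the 18.1% at summits beside neither muscle nor ribosomal protein genes (odds ratio 1.45, Fisher's exact p = 0.364).

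Summits lay mostly between genes. Of 3254 summits 2180 were intergenic (67.0% against 37.3% of the genome), 813 were in introns (25% against 33.1%) and 261 in exons (8.02% against 29.5%). Within 500 bp of a protein-coding start lay 1223 summits (37.6%, interval 35.9 to 39.3), 2.00 times the share of the genome (18.8%; exact binomial test, adjusted p = 1.78e-138). Intergenic sequence had exact adjusted p = 5.10e-256, introns 5.37e-24 and exons 4.12e-200.

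Chromosome X held the largest number of peaks. It carried 773 (23.8%, interval 22.3 to 25.3, against 17.7% of the length; exact adjusted p = 6.05e-18), or 43.6 per Mb. Chromosomes I (538 peaks, 35.7 per Mb, exact adjusted p = 0.0208) and III (502 peaks, 36.4 per Mb, adjusted p = 0.00894) were also above their share. Chromosomes V (468 peaks, 22.4 per Mb, exact adjusted p = 1.29e-20) and IV (464 peaks, 26.5 per Mb, adjusted p = 2.14e-06) were below it, and II (509 peaks, 33.3 per Mb) did not differ (adjusted p = 0.526). On X the top peaks of replicates 1 and 2 numbered 749 and 768.

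Genes for transfer RNAs and small nucleolar RNAs often lay beside a peak. A summit lay in or within 250 bp of 107 of 612 tRNA genes (17.5%) and 65 of 346 snoRNA genes (18.8%), against 4.73% of protein-coding starts. The windows of the non-coding genes were longer by the gene itself, so part of the difference may come from their length. The odds ratios were 4.27 (exact adjusted p = 3.96e-29) and 4.66 (adjusted p = 2.17e-20). For snRNA genes the count was 11 of 129 (exact adjusted p = 0.0953), for microRNA genes 17 of 261 (adjusted p = 0.231) and for rRNA genes 0 of 20. With the top peaks of replicate 1 alone snRNA genes passed the threshold (odds ratio 3.22, exact adjusted p = 0.00122), and with the peaks found in both replicates' top lists, an alternative chosen after seeing the data, snRNA (3.71) and microRNA genes (2.59) did.

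The replicates shared part of their strongest sites. The hlh-1 peaks ranked 1 and 2 in both, while the peak beside unc-14 ranked 97 in replicate 1 and 10 in replicate 2, and that beside M05D6.9 ranked 155 and 16. Of the top 3254 peaks of replicate 1, 1602 (49.2%) overlapped a top peak of replicate 2. The mean over 1000 shifts was 2.12% (one-sided permutation p = 0.001, the smallest these shifts can give). The shifts do not keep peaks between genes and near starts, where the real summits mostly lie. The test therefore does not separate shared HLH-1 sites from a shared preference for such sequence. Between the top 1000 peaks of each replicate the overlap was 58%, and requiring 50% of each peak lowered that of the top 3254 to 35.1%. Peaks of the full relaxed list of replicate 1 overlapped 2706 IDR peaks (83.2%), and those of replicate 2 overlapped all but 1. The IDR list was derived with these lists, which also hold background, so high shares are built in. The top lists of replicates 1 and 2 had 52.6% and 93.6% of their peaks in the IDR list. Across the 2706 peaks matched in both, Spearman's rho of the scores was 0.466 and Pearson's r of their log10 values 0.534; peaks are not independent replicates. Spearman's rho of the IDR score was 0.570 with replicate 1 and 0.961 with replicate 2.

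**Figure D4:**
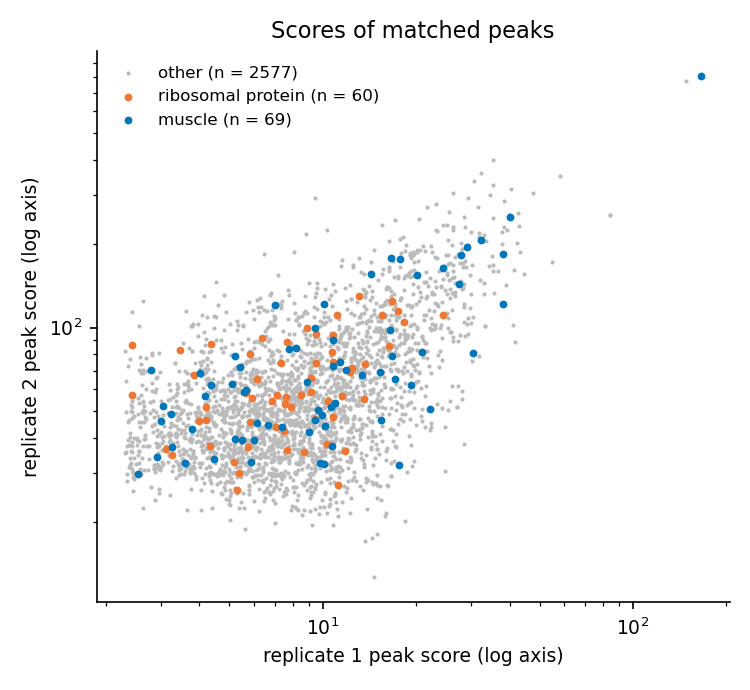
Authors' peak scores in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 2706 IDR peaks matched in both, coloured by whether the summit lies beside a muscle gene, a ribosomal protein gene or neither. Spearman's rho is 0.466, and the 2 points at the upper right are the hlh-1 peaks.

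Beyond the IDR list, CAGCTG stayed above its flank further down in replicate 2 than the ranks where it did in replicate 1; the difference between replicates was not tested. Among replicate 2 peaks outside the list it did so in each bin of 1000 down to rank 4000, with ratios of 2.04, 2.63, 2.74 and 2.22, but not from 4001 to 5000 (ratio 1.13, exact adjusted p = 0.782). In replicate 1 only ranks 1 to 1000 exceeded the flank (45 against 23 windows, ratio 1.96, exact adjusted p = 0.0184).

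The unc-119 locus, whose rescue marks the transgene, held peaks inside the gene. Within 20 kb of its start lay 4 summits, as many as or more than at 96.9% of protein-coding starts, and all 4 were in the gene (chromosome III, 10902641 to 10908935). Summits at 10905363 (score 121.6), 10906539 (score 166.5) and 10907347 (score 55.4) were in introns, and that at 10908690 (score 34.3) was in a coding exon. The number at hlh-1 reached or exceeded that at 99.9% of starts.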

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

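The tests of explanations in this part used predictions written before their values were seen, except the exon test for muscle gene bodies and the whole-peak test for sarcomere genes, which were chosen afterwards. Of the signal outside the IDR list, 3 items were flagged, and the further bins of replicate 2 are given above. The relaxed list of replicate 2 held 25 peaks on the mitochondrial genome (best rank 15, highest score 285), and that of replicate 1 held 0. CAGCTG exceeded its flank at peaks outside the IDR list, by 1.96 times at the first 1000 such peaks of replicate 1. At the first 1000 of replicate 2, which lie at other depths of its list, the ratio was 2.04. Of the top 3254 peaks of replicate 1, 1542 were outside the IDR list, and CAGCTG at these was 1.68 times its flank (57 against 34 windows, exact McNemar p = 0.0192), between the bounds of 1.5 and 2 set in advance for noise and for bound sites, against 11.96 times at the 1712 inside.

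Peaks gathered around hlh-1, a locus that the transgene may copy. Without the 2 strongest peaks, 6 summits remained within 20 kb of hlh-1, against a median of 1 over all protein-coding starts, as signal spread over extra copies of the segment would give. Of these, the outermost lay 17883 bp upstream of the start, in a coding exon of camt-1, 11850 bp upstream, in intergenic sequence, and 4205 bp downstream, beyond the end of hlh-1 in a coding exon of B0304.4. The extent of the copied segment is not in the labels, so whether it reaches these is unknown. At unc-119, the other locus, the number of summits reached the 96.9th percentile, between the bounds of 90 and 99 set in advance, so extra copies of that sequence could not be separated from chance crowding by this test. Binding of HLH-1 to its own gene remains open as a biological reading and was not tested.

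Summits beside sarcomere genes lacked CAGCTG: 0 of 33 against 15.5% of the 3108 summits beside neither muscle nor ribosomal protein genes (Fisher's exact test, p = 0.00638, a comparison made after seeing the counts). The top peaks of replicate 1 alone gave 0 of 20 against 10.4%, not past the threshold (Fisher's exact p = 0.256). Those of replicate 2 alone gave 1 of 35 against 15.45% (Fisher's exact p = 0.0336). These comparisons were not matched for position, since sarcomere summits all lie in start windows and the others need not. Of the summits with CAGCTG 27% lay within 500 bp of a start, against 37.6% of all summits, so part of the lack may come from position. CAGCTG lay anywhere in the peak in 1 of the 33 (3.03%, interval up to 15.3%), against 21.3% of those 3108 peaks (Fisher's exact p = 0.00824), and in 0 of 20 against 19.9% with replicate 1 alone (exact p = 0.0211), which argues against summits placed away from a site within the peak. The 79 muscle summits as a whole were not detectably short of CAGCTG (11.4%, exact p = 0.429); with replicate 1 alone the share was 3.57% (2 of 56) against 10.4% of other summits (exact p = 0.118). In these peaks it was 3 times as frequent as in equal intervals beside them (12 against 4, exact McNemar p = 0.0574), which decides nothing; the bound on p set in advance was not a fair exclusion with so few peaks. Bound muscle genes had a summit in the gene body 2.84 times as often as other bound genes of like length (23 of 63, permutation p = 0.0001, the smallest that 10000 draws can give), as signal over transcribed genes would give. Yet 13.3% of these 30 summits were in exons, against 49.8% of the body length (exact binomial p = 5.97e-05), which argues against signal spread evenly over the genes. Exons were depleted more than introns over the whole IDR list as well (8.02% of summits against 29.5% of the genome, and 25% against 33.1% for introns). A lack of exon summits is therefore not particular to muscle genes. These shares are of the whole genome and not of gene bodies, so the degrees of depletion cannot be compared. Intronic regulatory sites may account for the same values, and the control library was not analysed here.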

How the results depend on the processing

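The 29 results were recomputed under 152 alternatives, and 141 kept their direction and their side of the threshold. Among these, the CAGCTG ratio ranged from 5.42 to 17.1, the odds ratio of sarcomere genes from 14.7 to 59.2, of ribosomal protein genes from 8.82 to 51 and of tRNA genes from 3.01 to 3.99. Each gene list whose odds ratio crossed 1 was not past the threshold in any setting. With the window of 1000 bp upstream to 200 bp downstream, myogenic regulators had an odds ratio of 0.895 and germline genes 1.04. Germline genes had 1.59 in the upper part of the list by score and 1.64 with peaks in both top lists, and histone genes 0.982 with the nearest start alone. Leaving out either replicate gave 0.50 to 1.03 for neuronal genes, 0.962 to 1.78 for microRNA genes, 1.86 to 3.22 for snRNA genes (past the threshold without replicate 2) and -3.41 to 4.49 percentage points for CAGCTG at muscle against ribosomal protein summits. With peaks in both top lists, chosen after seeing the data, snRNA (3.71) and microRNA genes (2.59) passed the threshold. The cause of these changes was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, and with 2 replicates of unequal weight the IDR list mostly follows replicate 2.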

Other observations

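The tests of gene families, of paired hexamers and of GAGAGA below were chosen after the data were seen, and the p-values of the hexamer tests are not adjusted. The 3 tests on ribosomal protein peaks were written before their values were known. Protein-coding genes were grouped by the letters of their symbols, giving 175 families of at least 10 genes, of which 22 were bound more often and 18 less often than other genes (Fisher's exact test, Benjamini-Hochberg over the families). Besides the ribosomal families, the families with the lowest p among those bound more often were the unc genes, named for uncoordinated movement, with 43 of 94 bound (odds ratio 5.83, exact adjusted p = 2.36e-13), of which 22 were in the muscle lists, the let genes with 15 of 34 (odds ratio 5.41, adjusted p = 0.000125), the sup genes with 8 of 11 (odds ratio 18.3, adjusted p = 0.000142) and the tag genes with 18 of 57 (odds ratio 3.16, adjusted p = 0.00214). Of the 68 unc genes in no muscle list 21 were bound (30.9%; odds ratio 3.14, exact p = 5.4e-05, against all other genes in no muscle list). Other families bound more often included the secretory sec genes (9 of 19, exact adjusted p = 0.00273), nuclear pore npp genes (10 of 26, adjusted p = 0.00717), Mediator mdt genes (9 of 20, adjusted p = 0.00388), rab GTPases (9 of 20, adjusted p = 0.00388), eif translation factors (9 of 25, adjusted p = 0.0167), heat shock hsp genes (8 of 22, adjusted p = 0.0234) and proton pump vha genes (7 of 20, adjusted p = 0.0422). The mitochondrial ribosomal mrpl (11 of 41, exact adjusted p = 0.0645) and mrps genes (6 of 29, adjusted p = 0.436) did not pass. Among the families bound less often were the nuclear hormone receptors nhr (13 of 269, exact adjusted p = 0.000278), cyp cytochromes (0 of 74, adjusted p = 0.000937), clec lectins (7 of 240, adjusted p = 3.7e-06) and fbxa F-box genes (2 of 170, adjusted p = 1.32e-06).

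CAGCTG and GACGCA tended to mark different summits. Both occurred at 52 summits, where 72.9 would be met if they were independent (odds ratio 0.641, Fisher's exact test, p = 0.00374). Of the summits with CAGCTG 27% lay within 500 bp of the nearest protein-coding start, and of those with GACGCA 44.8%. GAGAGA was present at 27 of 79 summits beside muscle genes (34.2%) and at 7 of 67 beside ribosomal protein genes (10.4%; Fisher's exact test, p = 0.000764). At the summits beside neither group it was present in 30%, from which the ribosomal protein summits differed (odds ratio 0.272, Fisher's exact p = 0.000221) and the muscle summits did not detectably (odds ratio 1.21, exact p = 0.456).

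Why ribosomal protein genes carry peaks was tested in 3 ways, and none decided it. Their CAGCTG share was 3.93 points below that of muscle summits, within the 10 points set in advance for binding through CAGCTG, but it did not exceed its own flank detectably (5 against 2), and it was 7.46% against 15.5% at the summits beside neither group (odds ratio 0.439, Fisher's exact p = 0.0848). Anywhere in the peak it was 8.96% against 21.3% (exact p = 0.0143), and with replicate 1 alone 9.30% against 19.9% (exact p = 0.0853), a comparison made after the data were seen. The p-value stayed under 0.05 with replicate 2 alone (Fisher's exact p = 0.020) and with the peaks in both top lists (Fisher's exact p = 0.0365). Neither is a separate check, since 93.7% of IDR peaks overlap a top peak of replicate 2 and the peaks in both top lists are part of the IDR list. With replicate 1 alone the odds ratio was similar (0.412, against 0.364 in the IDR list) over fewer peaks (43 against 67). The comparison was not matched for position: ribosomal protein summits all lie in start windows, and the others need not. CAGCTG was less common near starts, as 27% of the summits with it lay within 500 bp of one, against 37.6% of all summits. The lower share may come partly from position, so it neither shows nor excludes less binding through CAGCTG than at the other peaks. A background common to both libraries was predicted to put these peaks relatively higher in replicate 1. The prediction took replicate 1 as the library with the weaker peaks, which rests on scores of unknown scale. The median shift in percentile rank of the ribosomal protein peaks was -4.92 points relative to muscle peaks (permutation p = 0.262). The direction was thus lower in replicate 1, opposite to the prediction, but not past the threshold, so such a background is not excluded. GACGCA was 1.68 times as frequent beside ribosomal protein as beside muscle genes (Fisher's exact p = 0.305), below the 2 times set in advance, although it was present at 10 of 67 summits and 0 flanks (exact McNemar p = 0.00195). It was no more frequent there than at the summits beside neither group (14.9% against 14.8%, odds ratio 1.01, exact p = 1), so it did not set these peaks apart.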
